A study of Arabidopsis thaliana with 12 samples.

How the data were processed

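RNA from roots of WT and hni9 plants held at low or high nitrogen was measured on 12 Affymetrix arrays, 3 biological replicates in each of the 4 groups of genotype and nitrogen supply. Groups, supplies and replicate numbers were taken from the labels. The titles of the hni9 arrays read hni9-1 for replicate 1, hni9-2 for replicate 2 and hni9 for replicate 3, while their genotype is given as hni9 throughout. Whether the number names an allele or a replicate is not given in the sources used here, so the spread between hni9 replicates could include a difference between alleles. Between numbers 1 and 2 limma called 1 probe set in hni9 and 0 in WT over 4 arrays each (1853 and 1458 at an unadjusted p under 0.05). With 4 arrays in a fit few calls can arise, so these counts do not decide on an allele difference. The difference between the numbers at high nitrogen had a correlation with that at low nitrogen of 0.0345 in hni9 and 0.00842 in WT. Among probe sets above the median mean it was 0.206 in hni9 and 0.0805 in WT. The values are the deposited intensity of each probe set on a linear scale, which the authors had scaled so that the mean of each array without its highest and lowest 2% of values is 500. That scaling was read from the values themselves, and the arrays were not quantile normalized. The summarisation software is not given in the sources used here. The deposited table holds 22810 probe sets, of which 64 control probe sets were left out and 22746 tested. The number of arrays limits the precision. On the log2 scale 10.8% to 15.0% of an array's values lay under the value of 16 that was added, so that changes of dim genes are compressed.

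Each intensity was transformed as log2(value + 16), with no further normalization between arrays. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, at a false discovery rate of 0.05. The comparisons were low against high nitrogen in WT and in hni9, hni9 against WT at high and at low nitrogen, their difference (the interaction, the change at high minus that at low nitrogen), and the nitrogen and genotype differences averaged over the other factor. Standard errors are those of limma after moderation of the variance. Means and standard deviations of intensities are on the linear scale.

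The annotation gave 1 gene to 13513 probe sets and several genes to 503, and did not list 8730. Of the 13513, 13436 were matched to a locus, and for 147 genes with more than 1 probe set the brightest was used. Counts of probe sets include those with no gene name. Of the named probe sets 110 carry the x suffix and 173 the s suffix, which mark probes that can bind transcripts of other genes, and AT2G41730 is one of the former. For HNI9 and NRT2.1 0 probe sets carried the gene's name, so both were not analysed here. Locus identifiers stand for genes that the annotation gives no other symbol.

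Genes were named by a fixed rule. For a comparison between 2 groups these were the 12 genes with the largest change in each direction among probe sets past the threshold with 1 annotated gene, all 3 arrays of one group above all 3 of the other, and the higher group's mean above the median of all probe sets. For 3 arrays against 3, chance alone gives such a separation in 10% of cases. The rule for the interaction was the same without the separation. From each gene list up to 4 members past the threshold with the smallest adjusted p were named, or up to 2 with the smallest p where none passed.

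Gene lists with at least 4 measured members were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction and compares it with no other genes. The adjustment was over the 35 lists tested in a comparison. Of these, 2 came from 26 lists fixed at the start, since few of their 332 genes carried a name in the annotation. Another 28 were annotation families written once that coverage was known and before any test of a gene, and 5 were written after values of genes had been seen. These 5 are the class III peroxidases, the hypoxia-induced genes, the berberine bridge enzyme-like genes, the major latex protein-like genes and the mitochondrial retrograde genes. The patterns that match family names were made insensitive to case after the first list results had been seen, which changed 2 families, none of which was called.

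Overlaps of calls were set against the product of the list sizes over the probe sets tested. The relation between the change of hni9 at high nitrogen and the nitrogen response of WT, whose contrasts share 3 arrays, was set against 100 simulations with no change. It was also computed over 6 splits that share no array. The mean squared change of a comparison was corrected by the variance between replicates, and the interval of the ratio of 2 such means was the 95% bootstrap interval over 1000 resamples of probe sets, which are not independent. Other splits of the arrays were counted over all 10 splits for comparisons of 3 with 3 arrays and over 100 drawn splits for the others. For the interaction the 100 splits were also run with the average genotype difference of each probe set removed. Positions of genes served to count neighbours, over 13217 placed genes and 500 shuffles. The fit and the list tests were tested on simulated data with known changes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

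The alternatives tried were the replicate number as a block, replicate 3 as a batch covariate, replicates 1 and 2 only, only the groups of a comparison in the fit, quantile normalization, arrays centred on their medians, the lowest 40% of probe sets left out, eBayes without trend or with robust estimation, array weights, a false discovery rate of 0.1, a change of at least 1 on the log2 scale, 1 or 64 in place of 16, and each array left out in turn. For lists they were the estimated correlation, fry and the mean of a gene's probe sets. The splits without shared WT arrays, and replicates 1 and 2 only for the relation of hni9 at high nitrogen to the WT response, were chosen after seeing the data. The arrays of replicate 3 have an empty description in the labels, unlike those of replicates 1 and 2. Arrays with the same replicate number in different groups had positive residual correlations, 0.022 to 0.103 for number 2, 0.023 to 0.067 for number 1 and 0.099 to 0.15 for number 3. Arrays of number 1 and number 2 in different groups also had mostly positive values, -0.003 to 0.051. A shift of number 3 alone brings this, since the deviations within a group cancel. On a principal component with 11% of the variance all arrays of number 3 had positive values and all others negative ones. The arrays of number 3 thus share a shift, and one of number 1 or 2 is not shown apart from it. The labels state no pairs, so the main fit has no block, and the block and the batch covariate were run as alternatives.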

Results

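Transcript abundance was measured in roots of Arabidopsis thaliana with 12 arrays, each reporting 22810 probe sets. The design crossed 2 genotypes, the wild type (WT) and hni9, a mutant of HNI9/IWS1, a factor of transcript elongation, with 2 steady nitrogen supplies. High nitrogen was 10 mM NH4NO3 and low nitrogen was 0.3 mM KNO3. The supplies differ in the salt as well as in the amount, so effects of the amount and of the form of nitrogen cannot be told apart. Each of the 4 groups held 3 biological replicates. The median intensity of an array lay between 199 and 221, and the median standard deviation between replicates was 0.20 to 0.23 on the log2 scale. The ratio of the 3′ to the 5′ GAPDH control probe sets was 1.31 to 1.35 in the WT arrays at high nitrogen and 0.921 to 1.27 in the other 9 arrays. The number of arrays limits the precision. All changes below are log2 fold changes ± standard error with n = 3 arrays per group and adjusted p-values from limma. For each named gene of a comparison between 2 groups that came from the largest changes, all 3 arrays of one group lay above all 3 of the other.

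The nitrogen response of WT roots asks what differs between the 2 supplies in the wild type. Genes of mitochondrial stress stood among the strongest rises at low nitrogen. AT2G21640, an oxidative stress marker, rose by 3.30 ± 0.34 (adjusted p = 3.36e-05), from an intensity of 212 ± 80.4 to 2141 ± 217 (SD). NDB4, an alternative NAD(P)H dehydrogenase of mitochondria, rose by 3.37 ± 0.56 (adjusted p = 0.00213), or by 4.37 and 2.23 with 1 and 64 added to the intensities in place of 16. AT5G09570, which encodes a small cysteine motif protein, rose by 2.82 ± 0.27 (adjusted p = 2.09e-05), from 331 ± 70.6 to 2399 ± 93.2. The phosphatase gene AT4G32950 rose by 4.29 ± 0.23 (adjusted p = 1.44e-07), from 103 ± 37.0 to 2243 ± 139. The efflux carrier genes AT2G04050 and AT5G52050 rose by 2.96 ± 0.29 and 2.94 ± 0.45 (the latter 3.80 and 1.88 with 1 and 64 added), and the aspartyl protease gene AT5G48430 by 2.78 ± 0.20. In the other direction, the lipid-recognition domain gene AT2G16005 changed by -3.01 ± 0.26 (adjusted p = 6.52e-06). The defensin gene PDF2.1 changed by -2.90 ± 0.23, the lectin gene AT3G16530 by -2.23 ± 0.16 and the berberine bridge enzyme-like gene AT5G44400 by -2.03 ± 0.11.

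In all, 1305 of 22746 probe sets passed a false discovery rate of 0.05 in WT, 646 higher and 659 lower at low nitrogen, and 470 of them changed at least 2-fold. With arrays centred on their medians the split was 765 higher and 517 lower. Of 7 mitochondrial retrograde genes, which are known to rise when mitochondria are impaired, 6 rose and 1 did not pass. Their median change was 2.96 (camera adjusted p = 1.32e-16; adjusted p = 0.0418 with an estimated correlation). That list was written after these values had been seen, so it is not independent evidence. Of 14 major latex protein-like genes, a list also written after the values were seen, 5 fell, among them AT4G23670 at -1.64 ± 0.11 and AT4G14060 at -1.33 ± 0.18. Their median was -0.67 (camera adjusted p = 1.29e-05; adjusted p = 0.0801 with an estimated correlation). Of 69 plastid-encoded genes, 6 fell, with a median of -0.30 (camera adjusted p = 4.17e-07; adjusted p = 0.543 with an estimated correlation, and 0.113 under fry). Of 11 nitrate and peptide transporter family genes, 3 fell, among them AT1G59740 at -1.54 ± 0.18 (camera adjusted p = 0.0275; adjusted p = 0.333 with an estimated correlation). Of 18 expansins, 3 fell and 1, EXPA9, rose by 0.64 ± 0.12 (camera adjusted p = 0.0275; adjusted p = 0.341 with an estimated correlation). The transporter family lost its call without WT replicate 1 or 3 at high nitrogen (0.0574 and 0.116) or WT replicate 1 at low nitrogen (0.0732), and the expansins without the same arrays (0.0562, 0.0611 and 0.0732) or WT replicate 3 at low nitrogen (0.0502). The count of 1305 was 413 with replicates 1 and 2 alone, 795 without the intensity trend of the variance, 820, 807 and 861 without WT replicates 1, 2 and 3 at high nitrogen, and 779 without WT replicate 2 at low nitrogen.

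The nitrogen response of hni9 roots asks the same of the mutant. AT4G32950 rose by 3.61 ± 0.23 (adjusted p = 9.38e-07), to 2209 ± 821 at low nitrogen. AAH, an allantoate amidohydrolase that recycles purine nitrogen, rose by 1.51 ± 0.12 (adjusted p = 6.45e-06), and GAMMA-VPE, a vacuolar processing protease, rose by 1.52 ± 0.12 (adjusted p = 7.19e-06). The auxin-conjugating enzyme gene GH3.3 changed by -2.84 ± 0.38 (adjusted p = 0.000373), or -3.44 without hni9 replicate 2 at high nitrogen, and PDF2.1 by -2.69 ± 0.23. The peroxidase genes AT1G49570 and AT5G64110 changed by -2.64 ± 0.15 and -2.37 ± 0.22, the pectate lyase gene AT3G27400 by -2.59 ± 0.27, and the lipid transfer gene AT4G12490 by -2.18 ± 0.30. In all, 1160 probe sets passed, 678 higher and 482 lower, 398 of them at least 2-fold. The split was 779 and 359 with arrays centred on their medians. Of the 35 lists 0 passed under camera in hni9 and 0 under fry, with 6 at an unadjusted camera p under 0.05. The mitochondrial retrograde genes had the lowest of these, with a median change of 0.48 (camera adjusted p = 0.0502). The count of 1160 was 362 with replicates 1 and 2 alone, 439 with only the hni9 arrays in the fit, 647 without the intensity trend, and 734 without hni9 replicate 1 at low nitrogen.

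The nitrogen responses of the genotypes overlapped. Of the probe sets called in each, 247 were higher at low nitrogen in both genotypes, against 19.3 for independent lists, and 206 were lower in both, against 14.0. The changes in hni9 and WT had a Pearson correlation of 0.327 (Spearman 0.242) across 22746 probe sets, which are not independent replicates. It was 0.507 with the dimmest 40% of probe sets left out. Over the 2035 probe sets called in the response averaged over genotypes (1048 higher, 987 lower, or 1335 and 739 with centred arrays), the slope of hni9 on WT was 0.883. That average compared 6 arrays with 6, and its probe sets were chosen on the same arrays as the slope. Over the probe sets called in WT, a choice that by itself favours the larger value in WT, the median was 0.72 in WT and 0.43 in hni9 for those higher, and -0.85 and -0.35 for those lower. The count of 2035 was 1000 with replicates 1 and 2 alone.

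**Figure D1:**
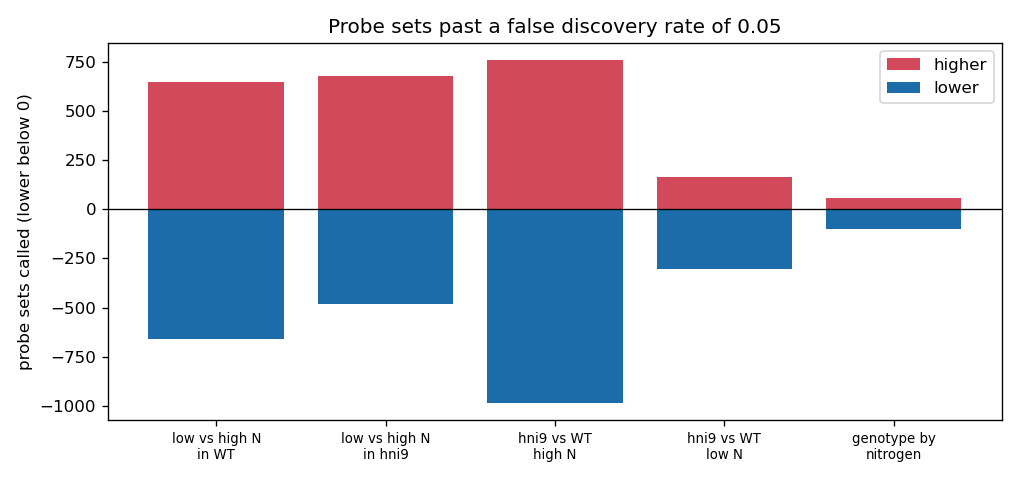
Number of probe sets past a false discovery rate of 0.05 in each comparison, with those higher drawn above 0 and those lower drawn below 0. The hni9 mutant differed from WT in 1744 probe sets at high nitrogen and in 469 at low nitrogen.

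The comparison of hni9 with WT at high nitrogen asks how the mutant differs where nitrogen is ample. The labels do not state the kind of mutation, and HNI9 itself was not analysed here. TPS-CIN, a cineole synthase of terpenoid metabolism, changed by -4.21 ± 0.39 (adjusted p = 1.52e-05), from 910 ± 217 in WT to 42.0 ± 33.0 (SD) in hni9. The acyltransferase gene AT1G78990 changed by -3.85 ± 0.30 (adjusted p = 3.28e-06), and the methyltransferase genes AT5G37990 and AT5G38020 by -2.90 ± 0.24 and -2.45 ± 0.35. Without hni9 replicate 3 at high nitrogen TPS-CIN had -3.56, and with replicates 1 and 2 alone -3.40. With 1 and 64 added in place of 16, TPS-CIN had -5.07 and -3.23, AT1G78990 -5.27 and -2.51 and AT1G52820 -4.08 and -2.11. The oxoglutarate-dependent oxygenase gene AT1G52820 changed by -3.19 ± 0.40, and AT2G16005 by -3.77 ± 0.26, from 1694 ± 151 to 116 ± 55.5. Among the rises, ICL, the isocitrate lyase of the glyoxylate cycle, rose by 2.34 ± 0.35 (adjusted p = 0.00108), from 159 ± 15.0 to 876 ± 148. The oxygenase gene AT5G43450 rose by 2.37 ± 0.23, the patatin-like gene AT5G43590 by 2.31 ± 0.28 and the peroxidase gene AT1G49570 by 1.96 ± 0.15. The chitinase genes ChiC and AT2G43600 rose by 1.82 ± 0.16 and 1.58 ± 0.15, and the small heat shock gene AT2G29500 by 1.56 ± 0.25.

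At high nitrogen 1744 probe sets passed, 759 higher and 985 lower in hni9, and of the 440 that changed at least 2-fold 103 were higher and 337 lower. With arrays centred on their medians the split of all calls turned, to 897 higher and 848 lower. Of 14 major latex protein-like genes 5 fell, among them AT4G14060 at -2.58 ± 0.18, with a median of -0.86 (camera adjusted p = 3.71e-07; adjusted p = 0.0635 with an estimated correlation). Of 55 class III peroxidases, secreted enzymes of the cell wall, 13 fell and 3 rose (camera adjusted p = 0.000964; adjusted p = 0.458 with an estimated correlation). AT2G41480 changed by -1.81 ± 0.17 and AT4G33420 by -1.27 ± 0.09. Of 7 mitochondrial retrograde genes 2 rose, among them AT5G51440 by 0.70 ± 0.10 (camera adjusted p = 0.000451; adjusted p = 0.428 with an estimated correlation). These 3 lists were written after the values were seen. Of 69 plastid-encoded genes 9 fell (camera adjusted p = 2.97e-06; adjusted p = 0.458 with an estimated correlation). The 4 green tissue genes, markers of shoot material, had a median of -1.37 in the same comparison, with 0 passing over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.0469; adjusted p = 0.458 with an estimated correlation). That call was lost without WT replicates 1, 2 or 3 (0.109, 0.0576 and 0.0528) or hni9 replicates 1 or 3 (0.114 and 0.12) at high nitrogen, and without WT replicates 2 or 3 (0.0523 and 0.0552) or hni9 replicate 2 (0.0529) at low nitrogen. It was also lost under fry (0.193) and with the mean of a gene's probe sets (0.055). Of 11 RALF-like peptide genes 4 fell, among them RALFL32 at -0.86 ± 0.11 (camera adjusted p = 0.0327; adjusted p = 0.425 with an estimated correlation). Of 7 calmodulin-like genes 1, CML23, passed at -0.78 (camera adjusted p of the list = 0.0469; adjusted p = 0.458 with an estimated correlation). The WT arrays at high nitrogen, the reference here, had the GAPDH ratios of 1.31 to 1.35 given above, against 1.03 to 1.25 in hni9 at high nitrogen. The count of 1744 was 482 with replicates 1 and 2 alone, 929 without the intensity trend, 1093, 1048 and 1049 without WT replicates 1, 2 and 3 at high nitrogen and 1129 without hni9 replicate 1. The RALF-like call was lost without WT replicate 2 (0.0629) or hni9 replicate 2 or 3 (0.0811 and 0.0539) at high nitrogen, and the calmodulin-like call without WT replicate 3 (0.19) or hni9 replicate 1 or 2 (0.0913 and 0.305) at high nitrogen, WT replicate 2 or 3 (0.0523 and 0.0552) or hni9 replicate 1 (0.055) at low nitrogen. Under fry the adjusted p was 0.0705 for the peroxidases, 0.193 for the plastid-encoded genes and 0.147 for the calmodulin-like genes. The latter had 0.0614 after quantile normalization and 0.055 with the mean of a gene's probe sets, and the RALF-like genes 0.0719 with that mean. CML23 lost its call without WT replicate 2 or 3 (0.0837 and 0.13) or hni9 replicate 1, 2 or 3 (0.053, 0.104 and 0.0666) at high nitrogen.

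The same comparison at low nitrogen asks how the mutant differs where nitrogen is scarce. AT1G73600, a methyltransferase of phosphocholine synthesis, changed by -2.24 ± 0.11 (adjusted p = 7.99e-08), from 3987 ± 277 in WT to 828 ± 13.3 (SD) in hni9. The peroxidase gene PRX52 changed by -2.75 ± 0.40 (adjusted p = 0.0021), the lipid transfer gene AT4G12500 by -2.74 ± 0.27 (adjusted p = 7.6e-05), and AT5G09570 by -2.50 ± 0.27 (adjusted p = 0.000231). TPS-CIN changed by -2.52 ± 0.39. With 64 added PRX52 had -2.03. AT1G12010, an enzyme of ethylene synthesis, rose by 1.89 ± 0.18 (adjusted p = 6.66e-05), from 179 ± 12.5 to 713 ± 119. AT2G29500 rose by 1.94 ± 0.25, AT2G43600 by 1.16 ± 0.15 and the glutathione transferase gene GSTU28 by 1.13 ± 0.17.

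At low nitrogen 469 probe sets passed, 166 higher and 303 lower in hni9, and of the 165 that changed at least 2-fold 33 were higher and 132 lower. Of 55 class III peroxidases 10 fell and 2 rose, with a median of -0.46 (camera adjusted p = 1.39e-08; adjusted p = 0.176 with an estimated correlation). AT5G39580 changed by -1.87 ± 0.18 and AT1G44970 by -1.23 ± 0.15. Of 7 mitochondrial retrograde genes 4 fell, with a median of -1.51 (camera adjusted p = 1.67e-08; adjusted p = 0.152 with an estimated correlation), among them AT2G41730 at -1.74 ± 0.19. Of 11 hypoxia-induced genes, known to rise under low oxygen, 2 fell, among them AT1G33055 at -2.68 ± 0.25, or -2.09 with 64 added (camera adjusted p = 7.1e-05; adjusted p = 0.0509 with an estimated correlation). Of 14 major latex protein-like genes 3 fell (camera adjusted p = 0.0342; adjusted p = 0.34 with an estimated correlation), a call lost without WT replicate 1 (0.0919) or hni9 replicate 2 or 3 (0.235 and 0.112) at low nitrogen and under fry (0.0589). These 4 lists were written after the values were seen. The count of 469 was 83 with replicates 1 and 2 alone, 156 without the intensity trend, and 241, 213 and 187 without WT replicates 1, 2 and 3 at low nitrogen.

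The changes of hni9 at high and at low nitrogen had a Pearson correlation of 0.262 (Spearman 0.234) across 22746 probe sets, which are not independent replicates. Of the 1744 probe sets called at high nitrogen, 1431 (82.1%) had the same sign at low nitrogen. In both comparisons 174 probe sets were lower in hni9, against 13.1 for independent lists, and 59 were higher, against 5.54. The mean squared change of the mutant, less its noise, was 0.0985 at high and 0.0452 at low nitrogen, a ratio of 2.18 (95% bootstrap interval over probe sets 1.97 to 2.45). Averaged over both supplies, with 6 arrays against 6, 2141 probe sets differed between the genotypes, 1001 higher and 1140 lower in hni9, a split that turned to 1234 and 955 with centred arrays. That count was 727 with replicates 1 and 2 alone and 1255 without the intensity trend.

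The interaction, the hni9 change at high nitrogen minus that at low nitrogen, asks whether the mutant's change depends on nitrogen. The peroxidase gene AT1G49570 had the lowest adjusted p among the named genes. It rose by 1.96 in hni9 at high nitrogen and had -0.79 ± 0.15 at low nitrogen, an interaction of 2.75 ± 0.21 (adjusted p = 3.41e-05). The value at low nitrogen passed at an adjusted p of 0.013, but not without WT replicate 1 or 2 (0.0531 and 0.0705) or hni9 replicate 3 (0.0523) at low nitrogen. For AT5G09570 the interaction was 2.99 ± 0.39 (adjusted p = 0.00389), and its intensity at low nitrogen was 2399 ± 93.2 in WT and 420 ± 103 in hni9. The peroxidase genes AT5G64110 and AT5G64100 had 2.4 ± 0.32 and 1.22 ± 0.14, and the chitinase gene ChiC had 1.61 ± 0.23. On the negative side stood the acyltransferase gene AT1G78990 at -2.79 ± 0.43 (adjusted p = 0.00693), or -4.15 and -1.61 with 1 and 64 added, the oxidoreductase gene AT1G64590 at -1.71 ± 0.19, the peroxidase gene AT2G41480 at -1.66 ± 0.24 and the strictosidine synthase-like gene AT3G57020 at -1.59 ± 0.26.

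The interaction passed for 160 probe sets, 59 positive and 101 negative. Of the negative ones, 74 were lower in hni9 at high nitrogen and not called at low nitrogen. Of the positive ones, 29 were higher at high nitrogen and not called at low nitrogen. Called at low nitrogen alone were 21 positive ones, lower in hni9, and 11 negative ones, higher in hni9. Another 6 positive and 3 negative ones were called in opposite directions at the 2 supplies. Of the 160, 49 (30.6%) had the same sign at both supplies, in a selection that by itself favours differing signs. Of 7 mitochondrial retrograde genes 5 passed, all positive, with a median of 2.51 (camera adjusted p = 2.33e-13; adjusted p = 0.0806 with an estimated correlation). Of 14 major latex protein-like genes 4 passed, all negative, with a median of -0.87 (camera adjusted p = 0.000139; adjusted p = 0.127 with an estimated correlation). Both lists were written after the values were seen. With replicates 1 and 2 alone the count was 1, and no named gene passed, with AT1G49570 at an adjusted p of 0.0524 (3.41e-05 with all arrays and up to 0.000347 with 1 array left out). The count was 21 without the intensity trend, 15 positive and 6 negative, so that the split turned, and lay between 67 and 254 with 1 array left out: 77, 81 and 91 without WT replicates 1, 2 and 3 at high nitrogen, 76, 67 and 81 without those at low nitrogen, 88 and 254 without hni9 replicates 1 and 2 at low nitrogen, and 247 without hni9 replicate 2 at high nitrogen.

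**Figure D2:**
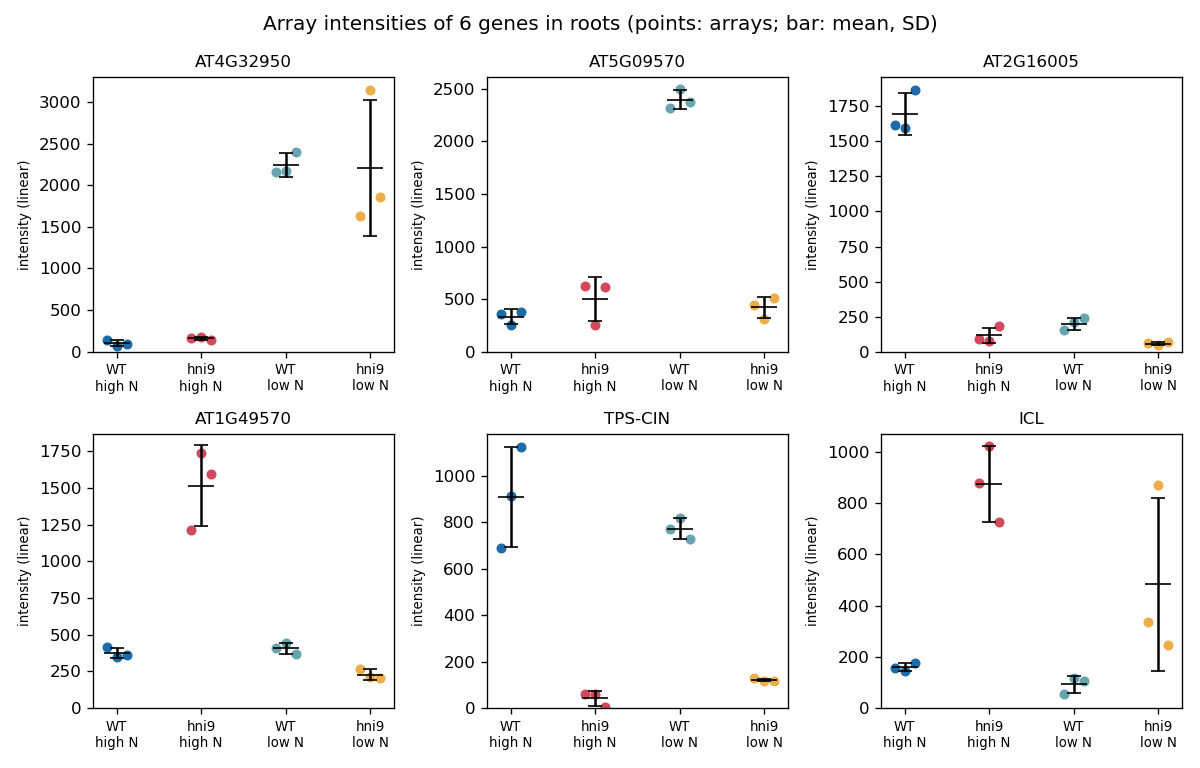
Linear intensity of 6 genes in each of the 12 arrays (points) with the mean and standard deviation of each group (bars), chosen after the values were seen. AT4G32950 rose at low nitrogen in both genotypes, AT5G09570 reached 2399 in WT and 420 in hni9 at low nitrogen, and TPS-CIN lay lower in hni9 at both supplies.

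The mutant's change at high nitrogen was set against the nitrogen response of WT, to ask whether hni9 fed with ample nitrogen shifts toward the state of low nitrogen. AT2G16005 and AT1G64370 were lower both in WT at low nitrogen (-3.01 and -2.89) and in hni9 at high nitrogen (-3.77 and -2.75). ChiC and AT5G43450 were higher both in WT at low nitrogen (1.65 and 2.39) and in hni9 at high nitrogen (1.82 and 2.37). Of 404 probe sets called in both comparisons, 332 changed in the same direction and 72 in opposite directions. Both comparisons share the WT arrays at high nitrogen, which alone brings a correlation and favours calls in the same direction. In 20 simulations with no change and the same shared arrays at most 0 probe sets were called in both. With no change hardly any call can arise, so these simulations do not measure how far sharing favours the same direction. The Pearson correlation was 0.397 (Spearman 0.380) across probe sets, and 0.499 in simulated groups with no change. The covariance was 0.0809 against 0.0447 in those simulations. With no WT array shared, its mean over 6 splits was 0.0333 ± 0.00250 (SD), from 0.0304 to 0.0364. The Pearson correlation in these splits was weak, from 0.113 to 0.1425. The splits reuse the same arrays, so this SD is not a spread between replicates.

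Of 332 genes in the 26 lists fixed before the data were examined, 35 were measured by a probe set with a gene name, and 2 lists reached the 4 members needed for a test. PGD3 and PGD1, dehydrogenases that supply reductant in the oxidative pentose phosphate pathway, rose at low nitrogen in WT by 0.96 ± 0.14 (adjusted p = 0.000618) and 0.63 ± 0.10 (adjusted p = 0.00128). GR1, a glutathione reductase, rose by 0.59 ± 0.10 (adjusted p = 0.00235), and the flavonoid glucosyltransferase gene UGT78D2 changed by -1.21 ± 0.19 (adjusted p = 0.00153). HHO3, a transcription factor gene of nitrate signalling, changed by -0.62 ± 0.12 at low nitrogen in hni9 (adjusted p = 0.00833, and 0.117 with replicates 1 and 2 alone), and HHO1 by 0.90 ± 0.25 (adjusted p = 0.048). In hni9 at low nitrogen HHO3 changed against WT by -0.51 ± 0.12 (adjusted p = 0.049). The call of HHO1 was lost without WT replicates 1, 2 or 3 (0.0647, 0.062 and 0.065) or hni9 replicates 1 or 2 (0.123 and 0.126) at high nitrogen, and without WT replicates 1, 2 or 3 (0.0686, 0.0722 and 0.0683) or hni9 replicates 1, 2 or 3 (0.129, 0.0759 and 0.129) at low nitrogen. That of HHO3 against WT was lost without WT replicates 1 or 2 (0.0698 and 0.055) or hni9 replicate 1 (0.0656) at high nitrogen, and without WT replicates 1, 2 or 3 (0.149, 0.105 and 0.166) or hni9 replicates 2 or 3 (0.14 and 0.0962) at low nitrogen. EXPA18, an expansin of root hair cells, was lower in hni9 at high nitrogen (-0.86 ± 0.13, adjusted p = 0.00102). NRT2.5, a high-affinity nitrate transporter gene, passed in none of the comparisons, at 0.32 ± 0.48 for low nitrogen in WT and 0.01 ± 0.48 for hni9 at high nitrogen. Of 7 class III glutaredoxins, 1 passed in hni9 at high nitrogen, GRXS4, higher by 2.15 ± 0.47 (adjusted p = 0.0122, and 0.0576 without WT replicate 1 at high nitrogen; 2.78 and 1.38 with 1 and 64 added), and 1 adjusted over the list alone; the list was not called there (camera adjusted p = 0.417) or in WT at low nitrogen (0 of 7 over all probe sets and 0 adjusted over the list alone, camera adjusted p = 0.339). In the nitrogen response of hni9 1 of the 7 passed, CEPD1, higher by 1.22 ± 0.31 (adjusted p = 0.0365), and 1 adjusted over the list alone (camera adjusted p of the list = 0.489). CEPD1 lost its call without WT replicate 2 (0.0517) or hni9 replicates 1, 2 or 3 (0.0592, 0.0527 and 0.137) at high nitrogen, and without WT replicates 1, 2 or 3 (0.054, 0.0554 and 0.052) or hni9 replicates 1, 2 or 3 (0.0806, 0.108 and 0.0831) at low nitrogen. In the interaction 0 passed and 1 did adjusted over the list alone (camera adjusted p = 0.869), and for hni9 at low nitrogen 0 and 0 (0.448). For the 4 green tissue genes the camera adjusted p outside hni9 at high nitrogen was 0.71 for low nitrogen in WT, 0.278 in hni9, 0.598 for hni9 at low nitrogen and 0.274 for the interaction, with 0 members passing, also adjusted over the list alone. Without hni9 replicate 1 at low nitrogen it was 0.034 for hni9 at low nitrogen, and without hni9 replicate 3 at low nitrogen 0.0282 for the interaction.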

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

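The counts over other splits of the arrays, the test on replicate 3 in the second pattern and the test of the whole WT group were chosen before their results were seen. The latter 2 tests use covariances with no shared array, an approach that was itself chosen after seeing the data. The splits with the average genotype difference removed and the other tests of the 3 patterns were chosen only after the results were seen. What drew attention to the results here is that the change between hni9 and WT differed between the nitrogen supplies by the interaction test, in 160 probe sets. In 100 drawn splits of the arrays 3, the real one included, gave as many calls, with 282 the highest of the others, but these splits do not test the interaction alone. The 2 that called more than the real one kept the arrays at high nitrogen in place and exchanged 2 of 3 WT arrays at low nitrogen with hni9 arrays, so that their contrast takes in the average genotype difference. With that difference removed from each probe set, 1 of the same 100 splits, the real one, gave as many as 160, with 1 call the highest of the others. That argues against chance but does not exclude it, since the removed difference was estimated with the real labels and this test was chosen after the planned one. With replicates 1 and 2 only 1 probe set was called. For the nitrogen difference averaged over genotypes 1 of 100 splits, the real one, gave as many as 2035, with 365 the highest other. For the genotype difference averaged over nitrogen 1 of 100, again the real one, gave as many as 2141, with 506 the highest other. Both argue against chance but do not exclude it, since 100 drawn splits can give no share below 1 in 100. In the other splits the real group differences also add to the spread, which lowers their counts. The 10 splits of 3 against 3 arrays are too few for a share under 0.05; the real counts were 1305 and 1160 for nitrogen in WT and hni9 and 1744 and 469 for hni9 at high and low nitrogen, with 0 the highest of the other splits in each.

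Of named genes, a positive interaction was found for AT5G09570 (2.99), AT1G49570 (2.75), AT4G12500 (2.66), AT2G41730 (2.51), AT2G04050 (2.51), AT5G64110 (2.4), AT1G33055 (2.34), AT5G43450 (2.04), ChiC (1.61), AT5G01740 (1.29), AT5G64100 (1.22) and AT5G51440 (1.03). A negative one was found for AT1G78990 (-2.79), AT2G16005 (-2.23), AT1G64590 (-1.71), AT2G41480 (-1.66), AT3G57020 (-1.59), AT4G14060 (-1.55), AT2G44940 (-1.49) and AT4G23680 (-1.09). These 20 passed with each array left out, and 0 of them with replicates 1 and 2 only.

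Another 12 lost the call without single arrays. AT2G21640 (2.82) lost it without WT replicate 2 at low nitrogen (adjusted p = 0.0563), as did AT5G43590 (2.35; 0.0518), and AT5G40590 (1.51) without WT replicates 1 and 2 at low nitrogen (0.0557 and 0.0676). UGT78D2 (-1.56) lost it without WT replicate 1 at high (0.0567) and 2 at low nitrogen (0.0676), and AT2G23910 (-2.35) without WT replicates 1 and 3 at high (0.0624 and 0.0667) and 2 and 3 at low nitrogen (0.0689 and 0.0549). For MSRB6 (-1.83) the arrays were WT replicates 1 and 2 at high (0.0757 and 0.0721) and at low nitrogen (0.0666 and 0.0707) and hni9 replicates 1 and 3 at low nitrogen (0.0579 and 0.0504). For AT1G19960 (-1.59) they were WT replicates 1, 2 and 3 at high (0.0993, 0.0862 and 0.0527) and 1 and 2 at low nitrogen (0.0725 and 0.0781). For CHIL (-1.56) they were WT replicates 1, 2 and 3 at high (0.0545, 0.0586 and 0.0692), 1 and 2 at low nitrogen (0.0704 and 0.0686) and hni9 replicate 1 at low nitrogen (0.0578). For AT4G33420 (-0.73) they were WT replicates 2 and 3 at high (0.0662 and 0.0692), 1 and 2 at low nitrogen (0.0725 and 0.075) and hni9 replicate 1 at low nitrogen (0.0518). AT3G26450 (-1.11) lost it without WT replicates 1 and 2 (0.085 and 0.0969) and hni9 replicates 1 and 3 (0.0587 and 0.078) at high nitrogen, and without WT replicates 1, 2 and 3 (0.0704, 0.0721 and 0.102) and hni9 replicate 1 (0.0873) at low nitrogen. AT4G23670 (-0.80) lost it without WT replicates 1, 2 and 3 (0.0926, 0.0859 and 0.0923) and hni9 replicates 2 and 3 (0.0523 and 0.0859) at high nitrogen, and without WT replicates 1, 2 and 3 (0.055, 0.0686 and 0.0918) and hni9 replicate 1 (0.0892) at low nitrogen. AT2G34810 (-2.42, or -3.17 and -1.51 with 1 and 64 added) kept it with hni9 replicate 1 at high nitrogen left out and lost it without WT replicates 1, 2 and 3 (0.118, 0.0901 and 0.129) and hni9 replicates 2 and 3 (0.0666 and 0.0798) at high nitrogen. It also lost it without WT replicates 1, 2 and 3 (0.117, 0.105 and 0.117) and hni9 replicates 1, 2 and 3 (0.131, 0.0572 and 0.0811) at low nitrogen.

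Of the lists, 6 differed between the supplies under camera, and 0 with an estimated correlation. The mitochondrial retrograde genes (adjusted p = 2.33e-13; 0.0806 with an estimated correlation) and the major latex protein-like genes (0.000139; 0.127) passed with each array left out. The plastid-encoded genes (0.00127; 0.856) did not without hni9 replicate 1 at low nitrogen (0.0626) or under fry (0.778). The hypoxia-induced genes (0.0281; 0.193) did not without hni9 replicates 1 and 2 at high nitrogen (0.0621 and 0.0588), WT replicates 1 and 2 (0.0823 and 0.0595) or hni9 replicate 3 at low nitrogen (0.0758), or with the replicate block (0.0704). The RALF-like genes (0.0281; 0.229) did not without WT or hni9 replicate 2 at high nitrogen (0.0676 and 0.0613), WT replicate 2 (0.0634) or hni9 replicates 1 and 3 (0.0626 and 0.0631) at low nitrogen, or under fry (0.0856). The subtilases (0.0284; 0.193) did not without WT replicates 1 and 2 (0.063 and 0.0676) or hni9 replicate 3 (0.113) at high nitrogen, WT replicate 2 (0.072) or hni9 replicates 1 and 2 (0.0626 and 0.0662) at low nitrogen, or under fry (0.151).

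The first pattern is that hni9 differed more from WT at high than at low nitrogen, by a ratio of mean squared changes of 2.18. More spread between the arrays at high nitrogen was argued against, since the ratio is computed less that spread. The spread itself, as the root of the mean variance, was 0.378 in WT and 0.412 in hni9 at high nitrogen, and 0.394 and 0.392 at low nitrogen. The interval of the ratio, with a lower bound of 1.97, is over probe sets and does not measure the spread between arrays. A single array was argued against too, since the lowest ratio with 1 array left out was 1.92, without WT replicate 3 at low nitrogen. The arrays of replicate 3 were not needed, since replicates 1 and 2 alone gave 1.94 and the other pairs of replicates 2.59 and 2.27. A departure of the whole WT group at high nitrogen, whose GAPDH ratios were 1.31 to 1.35, was not tested for this pattern and stays open. A role of HNI9 that differs between the 2 supplies is a candidate explanation. It was found on the same arrays, and the ratios above do not test it.

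The second pattern is that the change of hni9 at high nitrogen ran along the nitrogen response of WT, weakly where no array was shared (Pearson 0.113 to 0.1425). The WT arrays that both contrasts share were argued against as the whole cause, since the lowest of 6 covariances with no shared array was 0.0304, above 0, and the arrays of replicate 3 likewise, since the lower of 2 such covariances over replicates 1 and 2 was 0.0288. A departure of the whole WT group at high nitrogen cannot be told apart from a shift of hni9. Its test, the covariance of the hni9 change at high nitrogen with the nitrogen response of hni9, gave a mean of -0.0201 (-0.0249 to -0.0151), and a value below 0 also follows from a shift of hni9. That hni9 at high nitrogen may lie partly toward the state of low nitrogen stays open beside it.

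The third pattern is that mitochondrial retrograde genes rose at low nitrogen in WT and less in hni9, seen first in single genes and tested with a list written afterwards. On the log2 scale the WT arrays at low nitrogen had list medians of 10.56 to 10.64, and the other 9 arrays 7.22 to 9.31. The lowest of the former lay 1.25 above the highest of the latter, an hni9 array at high nitrogen. In these genes the rise was thus not that of a single WT array. At high nitrogen the list was already higher in hni9 than in WT (median change 0.77, camera adjusted p = 0.000451; adjusted p = 0.428 with an estimated correlation). Its array medians there were 7.82 to 9.31 in hni9 and 7.22 to 8.27 in WT. The smaller rise in hni9 and the interaction thus come in part from this higher level at high nitrogen. The list passed with each array left out (highest camera adjusted p = 3.93e-15 in WT and 2.42e-11 for the interaction). With an estimated correlation it kept its call in WT, but not in the interaction (adjusted p = 0.0806) or for hni9 at low nitrogen (0.152). Of the 7 members 5 had been picked by a rule that asks all 3 WT arrays at low nitrogen to lie above those at high nitrogen. That rule did not compare them with hni9 arrays, but AT5G09570, AT2G21640, AT2G41730 and AT2G04050 were also named by the interaction rule. AT5G09570 was named for hni9 at low nitrogen too, where the rule asks for separation from the hni9 arrays. The gap and the p-values of the list thus partly restate the choice of its genes. A stress of the WT cultures at low nitrogen other than nitrogen stays open, since culture and group coincide and the hypoxia-induced genes, another stress list, gave no call in WT (camera adjusted p = 0.413). The same list was lower in hni9 at low nitrogen (median -0.48, camera adjusted p = 7.1e-05) and positive in the interaction (median 0.39, camera adjusted p = 0.0281). Both calls were lost with an estimated correlation (adjusted p = 0.0509 and 0.193). That mitochondrial signalling at low nitrogen may need HNI9 stays a hypothesis.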

How the results depend on the processing

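The alternative without shared WT arrays, and that of replicates 1 and 2 only for the relation of hni9 at high nitrogen to the WT response, were chosen after seeing the data; the others were planned. Across 9 main results, 166 of the values under an alternative were within and 45 beyond 1.5 times a count or beyond the spread of a correlation. A count cannot reverse, but the larger of higher and lower changed side in 17 settings, among them centred arrays for hni9 at high nitrogen (759 and 985 to 897 and 848), for genotype averaged over nitrogen (1001 and 1140 to 1234 and 955) and for nitrogen in WT (646 and 659 to 765 and 517), and no intensity trend for the interaction (59 and 101 to 15 and 6). In the order nitrogen in WT, nitrogen in hni9, hni9 at high nitrogen, hni9 at low nitrogen and the interaction, replicates 1 and 2 only gave 413, 362, 482, 83 and 1 probe sets, of which 394, 348, 461, 81 and 1 were also called with all arrays. They gave 1000 for nitrogen and 727 for genotype averaged over the other factor, and fewer arrays carry less power by construction. Without the intensity trend the counts were 795, 647, 929, 156 and 21, and 1255 for genotype averaged over nitrogen; the cause was not tested. A change of at least 1 on the log2 scale, which can only lower a count, left 470, 398, 440, 165 and, for the averages, 397 and 255. A false discovery rate of 0.1, which can only raise one, gave 2617 and 801 for hni9 at high and low nitrogen and 276 for the interaction. With only the groups of the comparison in the fit, nitrogen in hni9 gave 439 and nitrogen in WT 1832; the cause was not tested. Leaving out the lowest 40% of probe sets by mean raised the correlation of the hni9 with the WT nitrogen response from 0.327 to 0.507, and the cause was not tested. With 1 array left out, counts ranged from 779 to 1516 for nitrogen in WT, 734 to 1071 in hni9, 1048 to 1988 for hni9 at high and 187 to 616 at low nitrogen, 67 to 254 for the interaction, and 1596 to 2109 and 1613 to 2005 for the averages. The covariance of hni9 at high nitrogen with the WT response was 0.0333 with no WT array shared, beside 0.0361 less chance with all arrays, a move beyond its standard deviation over splits of 0.00250.

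With the replicate number as a block the counts were 1485, 1294, 2063, 623 and 234. With replicate 3 as a batch covariate they were 1452, 1258, 2007, 572 and 193. Replicate numbers pair no arrays by the labels, but 11 of 12 arrays had their closest array of another group among those with the same number. Of the 395 results for named genes, 9401 values under alternatives stayed on their side of the threshold, 639 lost a call and 82 gained 1, and 0 reversed. Of 60 named genes called for nitrogen in WT 47 were kept with each array left out, of 51 in hni9 41, of 60 for hni9 at high nitrogen 44, of 42 at low nitrogen 28, and of 32 for the interaction 20. For 31 list results, 79 values lost a call and 2 gained 1; the estimated correlation ended 21 of the calls, fry 9 and the mean of a gene's probe sets 3. Simulated changes of 0.5 on the log2 scale were recovered in 29.9% to 38.8% of changed probe sets in comparisons of 2 groups and in 7.46% for the interaction. Simulated changes of 1 were recovered in 86.6% to 92.5% and 52.2%. The changes were placed only in probe sets brighter than the median, so recovery in dimmer ones was not measured. The simulated noise was independent between arrays, with no shift of replicate 3. False calls made up 1.95% for nitrogen in WT, 4.46% in hni9 and 4.61% for hni9 at high nitrogen. They made up 8.07% for hni9 at low nitrogen and 6.36% for the interaction, both above the nominal 5%. Each share came from a single simulation, with 110 to 161 calls, and is imprecise. Results planned for HNI9 and NRT2.1 were not run, since both were not analysed here.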

Other observations

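The test of neighbouring genes was chosen only after results had been seen, as was the choice to describe the gene groups that come first. Of these, the SWEET list is an annotation family written before any test of a gene, and the berberine bridge enzyme-like list was written after values were seen. The sugar transporter gene SWEET13 rose at low nitrogen by 1.07 ± 0.18 in WT and 1.09 ± 0.18 in hni9 (adjusted p = 0.00219 and 0.00215), and SWEET2 by 1.04 ± 0.15 and 0.80 ± 0.15 (adjusted p = 0.000797 and 0.00592), n = 3 arrays per group with limma. Of 14 SWEET transporters 4 rose and 0 fell in each genotype, and the list was not called under camera in either (adjusted p = 0.0804 and 0.114). Under fry it was called in WT and not in hni9 (adjusted p = 0.022 and 0.0572). Of 22 berberine bridge enzyme-like genes, 1 rose and 1 fell in WT, 2 rose and 2 fell in hni9, and 4 were lower in hni9 at high nitrogen; the list was not called under camera in these or in the other comparisons (adjusted p = 0.49, 0.97, 0.185, and 0.301 for hni9 at low nitrogen and 0.869 for the interaction). Under fry it was called in WT (adjusted p = 0.0232) and in hni9 at high nitrogen (0.0205), and not in the nitrogen response of hni9 (0.0919), hni9 at low nitrogen (0.059) or the interaction (0.778).

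The arrays separated by nitrogen on the first principal component (18% of the variance) and by genotype on the next (16%). The 4 arrays of replicate 3 had positive values on the component after that (11%), between 18.6 and 41.6, and the other 8 negative ones, between -25.6 and -1.01. Of the probe sets called with replicates 1 and 2 alone, 97.6%, 98.6%, 97.7% and 100% had the same sign in replicate 3 for nitrogen in WT, nitrogen in hni9, hni9 at high nitrogen and hni9 at low nitrogen. The ratio of the 3′ to the 5′ Actin control probe sets lay between 5.22 and 15.1.

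Genes lower in hni9 at high nitrogen or on average lay next to each other on the chromosomes more often than in shuffled orders. Among the 533 placed genes lower in hni9 averaged over nitrogen, 45 pairs were adjacent, against a mean of 21.3 and a highest of 34 in 500 shuffles, and among the 460 lower in hni9 at high nitrogen 34 pairs, against 15.9 and 26. Among the 141 lower at low nitrogen 5 pairs were adjacent, against 1.55 and 6, which is within the shuffles. Genes lower at low nitrogen in WT also did so, with 17 pairs against 7.02 and a highest of 16, and 14 sets were tested. A linked chromosome segment that differs between hni9 and WT is a possible explanation. The densest window of 40 genes held 9 of them, above the upper 5% point of 8 but not the highest of 10 in the shuffles, and 19 of 500 shuffles held as many. For genes lower in hni9 at high nitrogen it also held 9, against a highest of 10, with 6 of 500 shuffles as large, and at low nitrogen 6, against a highest of 6, with 1 of 500 as large. No window held more than the highest of its shuffles, so the segment stays open, and tandem copies with like expression or probes shared between them were not tested.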
